A study of Capra hircus with 4 samples.

How the data were processed

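RNA was sequenced from secondary hair follicle stem cells of cashmere goats (Capra hircus), the cells of the follicles that grow the fine cashmere undercoat, after isolation from dorsal skin and culture. Total RNA was extracted with a TRIzol-type reagent and libraries were made with an NEB Ultra RNA kit, per the labels' protocols. The 4 libraries fall into 2 groups by their titles, early anagen sampled in April and mid anagen sampled in October. Each group has 1 female and 1 male library, which the labels call biological replicates. The replicate number is the same as the sex in both groups.

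The deposited values are a signal, namely a length-normalised abundance per gene, and not counts. kallisto 0.46.1 and sleuth 0.30.0 are named in the submitters' processing notes. The genome build, the annotation and the way transcripts were combined per gene are not given in the sources used here. Each library had 1 value for each of 20326 genes, and 3004 genes were at 0 in all libraries. The values behaved like TPM rescaled between libraries. Their totals were 1068429 in the early female, 1186966 in the early male, 933211 in the mid female and 844960 in the mid male library, while the median ratio of a gene to its geometric mean over the libraries lay between 0.9898 and 1.018. At the full precision of the files, 0 genes above 0 in both libraries of any pair had equal values. Of the gene identifiers, 20294 were found in the RefSeq table of the ARS1.2 goat assembly, which was used for gene spans, for names and to see which genes have no chromosome assigned. No coordinates are printed, since the build behind the values is not known.

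The number of reads per library is unknown, so no counting interval can be given. Low values were searched for the step that 1 read makes. Among 2192 genes under 0.6 in every library and above 0 in both early libraries, 13.4% of the female-to-male ratios fell in a single bin 0.05 wide on the log2 scale, at a ratio of 1.09. In the 3 pairs that include the mid male library the fullest bin held 2.7% to 3.34%, so relative depth was not recovered for that library.

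Values were analysed as log2(value + 1) in R 4.3.3 with limma 3.58.1. A fold change is therefore on the log2(value + 1) scale and understates the change of genes with low values. Genes with a value of at least 1 in at least 2 libraries were tested, which left 12486. A gene that reached 1 only in the libraries of 1 phase can only be higher in that phase, so the filter fixed its direction. Mid anagen was compared with early anagen by limma with an intensity trend, with phase as the only term. Male was compared with female in a fit with phase and sex. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A phase-by-sex interaction leaves no residual degrees of freedom and was not tested. Fold changes within each sex, called the female pair and the male pair, are given as values, and nothing in the labels says whether the 2 libraries of a pair come from related animals.

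Before the data were examined, 33 gene lists were fixed for follicle and skin cell types, signalling pathways, cell cycle, metabolism and stress. Of these, 31 had at least 5 tested members and were tested by camera with an inter-gene correlation of 0.01. The files hold no read counts, so the test planned for normalised values was used. The rule for named genes was fixed at the same time. It takes the 12 called genes with the largest positive and the 12 with the largest negative log2 fold change that have a symbol, a mean value of at least 5 and the same direction in both pairs, plus up to 4 members of each list with the smallest p and, for sex, the 5 genes with a symbol and the smallest p. Of the 18 genes that the phase part of the rule took by fold change, 1 is not reported here by name. Genes outside this rule are said to be so where they are named.

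The tests were checked on simulated data made for the comparison of mid with early anagen, with 12486 genes of which 200 were changed, in 20 simulations. The fit with phase alone recovered 13.7% of the genes changed 2-fold, 83.7% of those changed 4-fold and 95.3% of those changed 8-fold, with a mean of 6.85 false calls. The changed genes were drawn only from those with higher mean values, and their folds were set on the log2(value + 1) scale. Recovery of genes with low values was therefore not checked. The list test called 20 of 20 lists of 30 genes shifted by 0.5 on the log2 scale and 1 of 180 lists left unshifted. The simulated genes varied independently of each other, whereas the estimated correlation of the ribosomal protein list was 0.886. False calls among lists whose members move together were therefore not checked. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter of 5, leaving out each library, a replicate block, a fold-change minimum, an estimated inter-gene correlation, fry and other measures of library similarity. Rescaling each library to a common total, removing a trend with gene span and intensity, and limma without an intensity trend were added after seeing the data.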

Results

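Gene expression was measured in cultured secondary hair follicle stem cells of cashmere goats at 2 points of the growth phase of the hair cycle. The cells came from dorsal skin at early anagen in April and at mid anagen in October, with 2 libraries per phase, 1 from a female and 1 from a male. The question the design poses is how expression in these cells differs between the phases of cashmere growth. All values are deposited abundances per gene, and the read depth behind them is unknown. Genes at or above 1 numbered 12249 in the early female, 12040 in the early male, 12458 in the mid female and 12404 in the mid male library. The 13 mitochondrially encoded genes took 12.4% and 11.2% of the total in the early female and male and 16.6% and 14.2% in the mid female and male libraries.

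Over all tested genes, libraries of the same phase were closer to each other than libraries of different phases. Across 12486 genes, Pearson's r of log2 values was 0.9839 between the early libraries and 0.9718 between the mid libraries, against 0.9419 to 0.9661 between phases. Among the 1000 most variable genes this did not hold for every pair, with 0.9009 between the mid libraries and 0.9079 between the early and mid female libraries. These correlations are across genes, which are not independent replicates. The leading principal component held 67.7% of the variance, with the early libraries at -19.8 and -42.6 and the mid libraries at 31.2 and 31.1.

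Among the genes taken by the rule, matrix-related genes had the largest rises at mid anagen. FN1, fibronectin (GeneID 102182645), went from 0.247 in the early female and 1.10 in the early male to 92.0 and 61.7 at mid anagen, a log2 fold change of 5.56 (SE 0.32, limma adjusted p = 0.0245, n = 2 per phase). BGN, the matrix proteoglycan biglycan (GeneID 102183219), rose by 3.90 (SE 0.39, adjusted p = 0.0431), MXRA5, a matrix remodelling associated gene (GeneID 106503888), by 3.35 (SE 0.20, adjusted p = 0.0245), and EFEMP1, a fibulin (GeneID 102190700), by 3.34 (SE 0.24, adjusted p = 0.0323). Other rule genes that rose were FSTL1, a secreted follistatin-like protein, PLXDC2, FIBIN, TP53I11, the chemokine CX3CL1, OLFML3 and ID4, an inhibitor of basic helix-loop-helix factors. Their log2 fold changes ran from 2.74 for FSTL1 to 2.28 for ID4. FBN1, the microfibril protein fibrillin, was at 0.125 and 0.133 in the early female and male and at 8.48 and 5.86 at mid anagen. LOC102172205, described as serotransferrin and outside the rule for want of a symbol, was also called, with a log2 fold change of 3.79.

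Of the genes that fell, 6 met the rule. GRP, gastrin releasing peptide (GeneID 102174351), fell from 33.7 and 30.9 in the early female and male to 6.72 and 5.05, a log2 fold change of -2.28 (SE 0.18, adjusted p = 0.0323). FBP2, a fructose bisphosphatase (GeneID 102185744), changed by -1.93 (SE 0.16, adjusted p = 0.0323), and BNIP3, a mitophagy receptor induced by low oxygen (GeneID 102178036), by -1.69 (SE 0.17, adjusted p = 0.0431). FBXO2, an F-box protein, changed by -1.56, CIRBP, a cold-inducible RNA-binding protein, by -1.53, and KIAA0101, the PCNA clamp associated factor, by -1.42. LOC102174478, a gene without a description that was singled out after its values were seen, was at 20.2 and 28.1 in the early libraries and at 0.455 and 0.637 in the mid libraries.

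**Figure D1:**
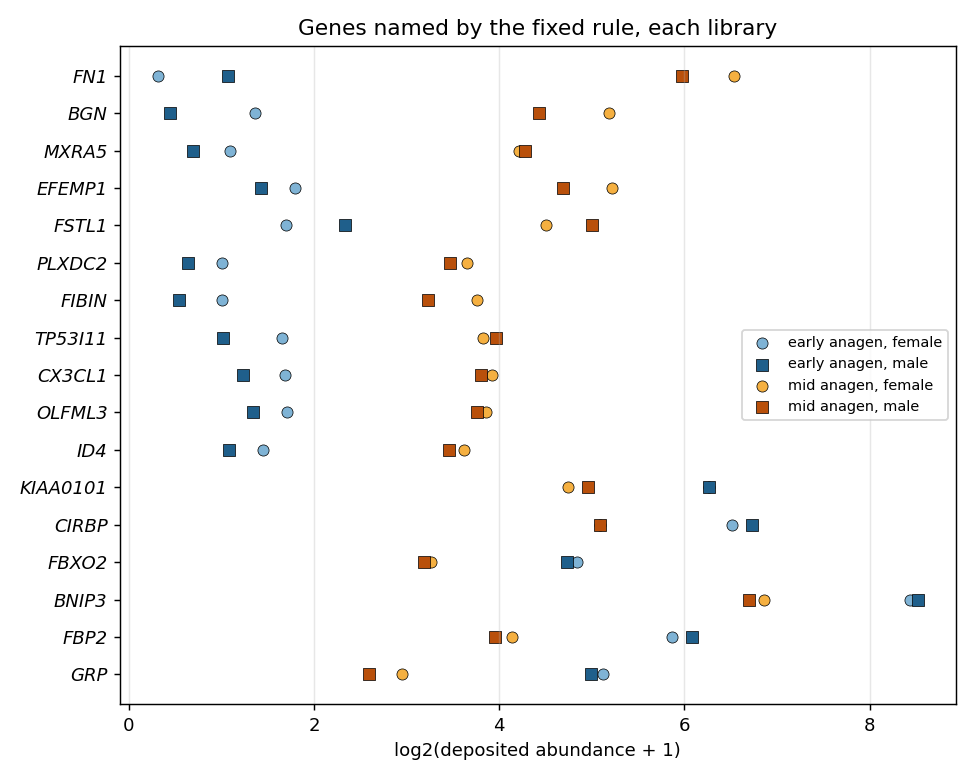
Each point is 1 library, with log2(deposited abundance + 1) on the horizontal axis and 17 genes named by the rule on the vertical axis. Early libraries are blue, mid libraries orange, females circles and males squares. In every gene shown both early libraries lie on the same side of both mid libraries. The rule took called genes with the same direction in both pairs, so this was largely fixed by the choice.

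In all, limma called 38 of 12486 genes, 28 higher and 10 lower at mid anagen, and 3482 genes had an unadjusted p under 0.05. All 38 had the same direction in both pairs. A call from 2 libraries per phase nearly requires this, so it is no separate support. A fit with sex as a second term called 1782 genes, 917 higher and 865 lower, including all 38, and rescaling each library to a common total gave 651 calls of which 87.3% were higher, against 73.7% as deposited. The rescaling moved the median log2 fold change of all tested genes by 0.31, from 0.01 to 0.32, and list medians shift with it. Leaving out the early female or the early male library left 0 calls (2897 and 1445 genes at an unadjusted p under 0.05), while leaving out the mid female or mid male library gave 733 and 370, including all 38. In each of these fits the spread comes only from the 2 libraries of the other phase, and the lone library is assumed to vary like them.

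Several lists of stem cell, signalling and matrix genes were higher at mid anagen, with 13 of 31 lists past the threshold in camera, 8 higher and 5 lower. The dermal papilla and fibroblast list rose most, with a median log2 fold change of 2.52 over 21 tested members (camera adjusted p = 6.74e-12, adjusted p = 0.508 with an estimated correlation). In it 4 members rose and 17 did not pass over all genes, and 18 rose when adjusted over the list alone. Those 4 were FN1, FBN1, TNC, the matrix glycoprotein tenascin, and COL5A1, a fibrillar collagen chain, which went from 3.49 and 2.76 to 16.1 and 18.4. COL1A1, a type I collagen chain named after its values were seen, was at 0.18 and 0.99 in the early female and male and at 58.6 and 19.8 at mid anagen. COL1A1 and FBN1 passed the filter only through the mid libraries. So did COL1A2, COL3A1, COL6A1, COL6A3, DCN, LUM, PRRX1, POSTN and VCAN, named here for that reason. A gene kept that way can only be higher, so the filter fixed part of the list's median, camera result and rises in advance. The list has 35 members in all. Of these SOX2, CORIN, ALPL, RSPO3, CRABP1, HHIP, SOX18, PDGFRA, FAP, TWIST1, ZEB1 and ZEB2 were under 1 in every library. PDGFRB reached 1 only in the mid female and CDH2 only in the mid male library. None of these genes was tested, so no rise is shown for them. The extracellular matrix remodelling list had a median of 0.87 over 37 members (camera adjusted p = 8.71e-08, adjusted p = 0.459 with an estimated correlation). TNC and BGN rose in it, 35 did not pass, and 18 rose adjusted over the list alone. LOXL1, a collagen cross-linking oxidase, was at 45.8 and 37.1 early and at 105 and 127 mid without passing over all genes.

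Markers of the hair follicle bulge, where the stem cells reside, had a median of 0.67 over 14 members (camera adjusted p = 1e-05, adjusted p = 0.508 with an estimated correlation). LHX2, a stem cell transcription factor, rose from 9.54 and 6.94 to 31.7 and 32.1 (log2 fold change 1.85, SE 0.18, adjusted p = 0.0431), 13 members did not pass, and 6 rose adjusted over the list alone. TCF7L1, a transcription factor of the WNT pathway, was at 2.39 and 1.17 early and 11.5 and 15.3 mid (adjusted p = 0.0551), and TBX1 at 4.62 and 2.10 early and 14.3 and 15.8 mid (adjusted p = 0.0699). Among the 14 tested members 12 were higher in both pairs and 0 were lower in both. LGR6, CD34, FOXI3, CD200 and ALDH1A1 were below the filter, and KRT15 was not found by its symbol. LOC102179515, outside the rule and described as type I cytoskeletal keratin 15, differed between the pairs. It went from 414 to 182 in the female pair and from 88.4 to 241 in the male pair.

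Among the signalling lists, BMP and TGF-beta signalling had a median of 0.51 over 39 members (camera adjusted p = 3.04e-07, adjusted p = 0.459 with an estimated correlation). ID4 and FSTL1 rose, 37 did not pass, and 11 rose adjusted over the list alone. GREM1, a BMP antagonist, was at 0.649 and 0.802 early and at 3.12 and 2.78 mid, and passed the filter only through the mid libraries. FGF, EGF and IGF signalling had a median of 0.43 over 37 members (camera adjusted p = 0.00408, adjusted p = 0.508 with an estimated correlation). In it the receptor FGFR1 rose by 1.85 on the log2 scale (SE 0.19, adjusted p = 0.0431), 36 members did not pass, and adjusted over the list alone 9 rose and 1 fell. Hedgehog signalling had a median of 0.28 over 9 members (camera adjusted p = 0.00609, adjusted p = 0.508 with an estimated correlation), with 0 past the threshold over all genes and 4 higher adjusted over the list alone. GAS1, a Hedgehog co-receptor, was at 0.461 and 0.483 early and at 3.28 and 3.59 mid. GAS1 and GLI2, both among those 4, passed the filter only through the mid libraries, so their direction was fixed. The camera call for Hedgehog ended when the span trend was removed (adjusted p = 0.13).

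Hormone and vitamin receptors had a median of 0.39 over 16 members (camera adjusted p = 0.0434, adjusted p = 0.508 with an estimated correlation). None of the 16 passed over all genes, and adjusted over the list alone 2 rose and 1 fell. VDR, the vitamin D receptor, was at 20.3 and 17.1 early and 47.5 and 58.6 mid, and PPARG at 11.3 and 11.4 early and 4.13 and 6.02 mid. The interferon response list had a median of 0.34 over 25 members (camera adjusted p = 0.0236, adjusted p = 0.508 with an estimated correlation), with 0 past the threshold over all genes, and 4 higher and 2 lower adjusted over the list alone. IFIT3 was at 3.72 and 1.77 early and 7.39 and 6.94 mid, and PSMB9, an immunoproteasome subunit, at 12.8 and 17.7 early and 6.79 and 8.995 mid. After rescaling to a common total both camera calls ended, with an adjusted p of 0.0868 for the receptors and 0.0851 for interferon. The receptor call also ended with the span trend removed (adjusted p = 0.28), and the interferon call without the mid male library (adjusted p = 0.0741).

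Most cell cycle genes had lower values at mid anagen. All 40 S phase genes were lower in both pairs, with a median log2 fold change of -0.70 (camera adjusted p = 5.26e-14, adjusted p = 0.508 with an estimated correlation). The G2/M list had a median of -0.73, with 37 of 40 genes lower in both pairs (camera adjusted p = 6.47e-13, adjusted p = 0.508 with an estimated correlation). In both lists 0 genes passed over all genes tested in the fit with phase alone, while 34 S phase and 31 G2/M genes fell adjusted over the list alone. With sex as a second term, 25 S phase and 23 G2/M genes were called lower over all genes. Rescaled to a common total, the medians were -0.38 for S phase and -0.40 for G2/M. PCNA, the replication clamp, was at 139 and 154 in the early female and male and at 60.0 and 81.3 at mid anagen, and CCNB1, a mitotic cyclin, at 208 and 245 early and 84.4 and 110 mid.

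Metabolic and ribosomal lists were also lower. The hypoxia and glycolysis list had a median of -0.52 over 30 members (camera adjusted p = 1.32e-06, adjusted p = 0.508 with an estimated correlation). BNIP3 fell, 29 members did not pass, and 15 fell adjusted over the list alone. After rescaling to a common total the list's median was -0.19. PDK1, a kinase that restrains pyruvate oxidation, was at 33.7 and 30.1 early and at 17.2 and 13.6 mid. Oxidative phosphorylation had a median of -0.75 over 20 members (camera adjusted p = 7.95e-07, adjusted p = 0.508 with an estimated correlation), with 0 past over all genes and 11 lower adjusted over the list alone, and a median of -0.41 after rescaling. All 74 tested cytosolic ribosomal protein genes were lower in both pairs, with a median of -1.08 (camera adjusted p = 6.65e-23, adjusted p = 0.508 with an estimated correlation), 0 past over all genes and 38 lower adjusted over the list alone. RPL9 was at 743 and 704 early and at 372 and 258 mid.

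The ribosomal median was -0.58 in the female pair and -1.46 in the male pair. Other abundant genes also varied with genomic span. Among 79 genes spanning up to 1500 bp with a mean value of at least 50, the median log2 fold change was -0.50 in the female pair and -1.12 in the male pair, and among 170 genes spanning over 100 kb it was 0.12 and 0.24. With the span trend removed the medians were -0.55 for ribosomal proteins and -0.41 for oxidative phosphorylation.

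**Figure D2:**
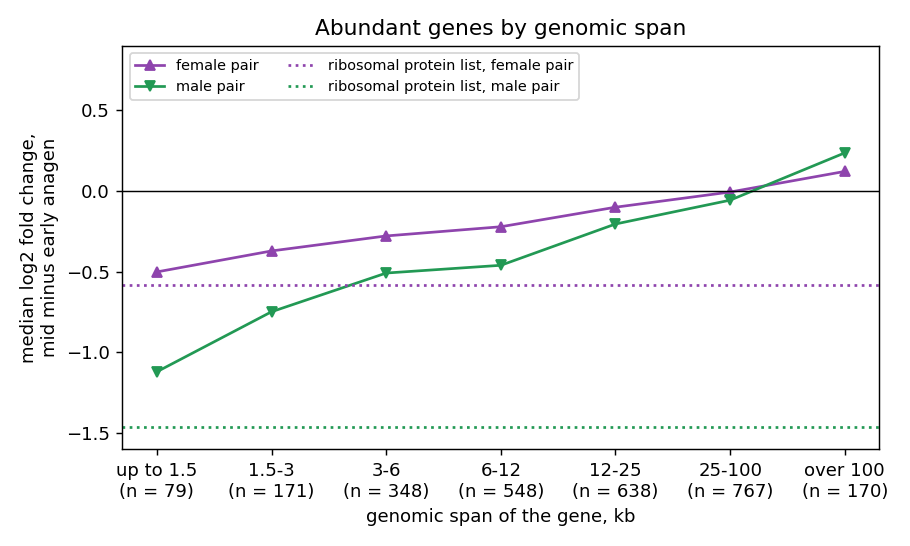
The median log2 fold change of mid against early anagen is plotted against genomic span for genes with a mean value of at least 50, with the members of the ribosomal, oxidative phosphorylation and cell cycle lists left out. Triangles pointing up are the female pair and triangles pointing down the male pair, which run from -0.50 and -1.12 in the shortest genes to 0.12 and 0.24 in the longest, and dotted lines mark the ribosomal list at -0.58 and -1.46.

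Lists of other cell types did not pass in camera apart from the fibroblast list. The median was 0.13 for smooth muscle and pericyte genes (adjusted p = 0.195), -0.05 for melanocyte (adjusted p = 0.745), 0.02 for immune cell (adjusted p = 0.637), 0.06 for adipocyte and sebocyte (adjusted p = 0.922) and 0.48 for nerve and Schwann cell genes (adjusted p = 0.106). The melanocyte mean was 0.23 and the direction of its test upward, against the sign of the median, and the median became 0.25 after rescaling to a common total. Only 2 endothelial genes could be tested, ERG at 0.884 and 0.333 early and 4.19 and 5.24 mid, and EGFL7 at 2.86 and 3.72 early and 7.10 and 5.16 mid. Neither passed over all genes and both rose adjusted over the list alone. ERG passed the filter only through the mid libraries. Adjusted over each list alone, 2 nerve and Schwann cell genes, S100B and ERBB3, 1 immune cell gene, CD14, and 1 smooth muscle and pericyte gene, CSPG4, rose, 1 adipocyte and sebocyte gene, PPARG, fell, and 0 melanocyte genes passed.

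Basal keratinocyte genes had a median of 0.05 and a mean of -0.03 (camera adjusted p = 0.922), with KRT14 at 20587 and 23511 early and 9603 and 8956 mid, a difference that did not pass. The median was 0.19 for hair lineage genes (adjusted p = 0.225), -0.36 for epidermal differentiation (adjusted p = 0.346), 0.16 for WNT (adjusted p = 0.0614) and 0.23 for Notch signalling (adjusted p = 0.106). The WNT receptor FZD1 rose from 2.27 and 1.32 to 14.0 and 10.6, and with sex as a term the WNT list passed at an adjusted p of 0.0393 (adjusted p = 0.677 with an estimated correlation in the fit with phase alone). DNA methylation and histone modifiers had a median of 0.12 (adjusted p = 0.165), with UHRF1, a maintenance methylation cofactor, at 82.7 and 77.7 early and 24.9 and 43.0 mid. The circadian clock list had a median of 0.30 (adjusted p = 0.128) and the p53, arrest and senescence list 0.07 (adjusted p = 0.178). Cholesterol synthesis had a median of -0.30 (adjusted p = 0.106), which became 0.04 after rescaling to a common total. Medians were 0.05 for immediate early and heat shock genes (adjusted p = 0.593), 0.24 for the unfolded protein response (adjusted p = 0.637), 0.27 for inflammatory cytokines (adjusted p = 0.133) and 0.11 for mitochondrially encoded genes (adjusted p = 0.442). With the span trend removed, 4 lists passed that had not as deposited, all upward, namely mitochondrially encoded genes (camera adjusted p = 1.38e-06), immediate early and heat shock genes (adjusted p = 0.00089), p53, arrest and senescence (adjusted p = 0.00887) and the unfolded protein response (adjusted p = 0.0241). As deposited, their adjusted p with an estimated correlation was 0.508 for p53, arrest and senescence and 0.811 for each of the others.

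**Figure D3:**
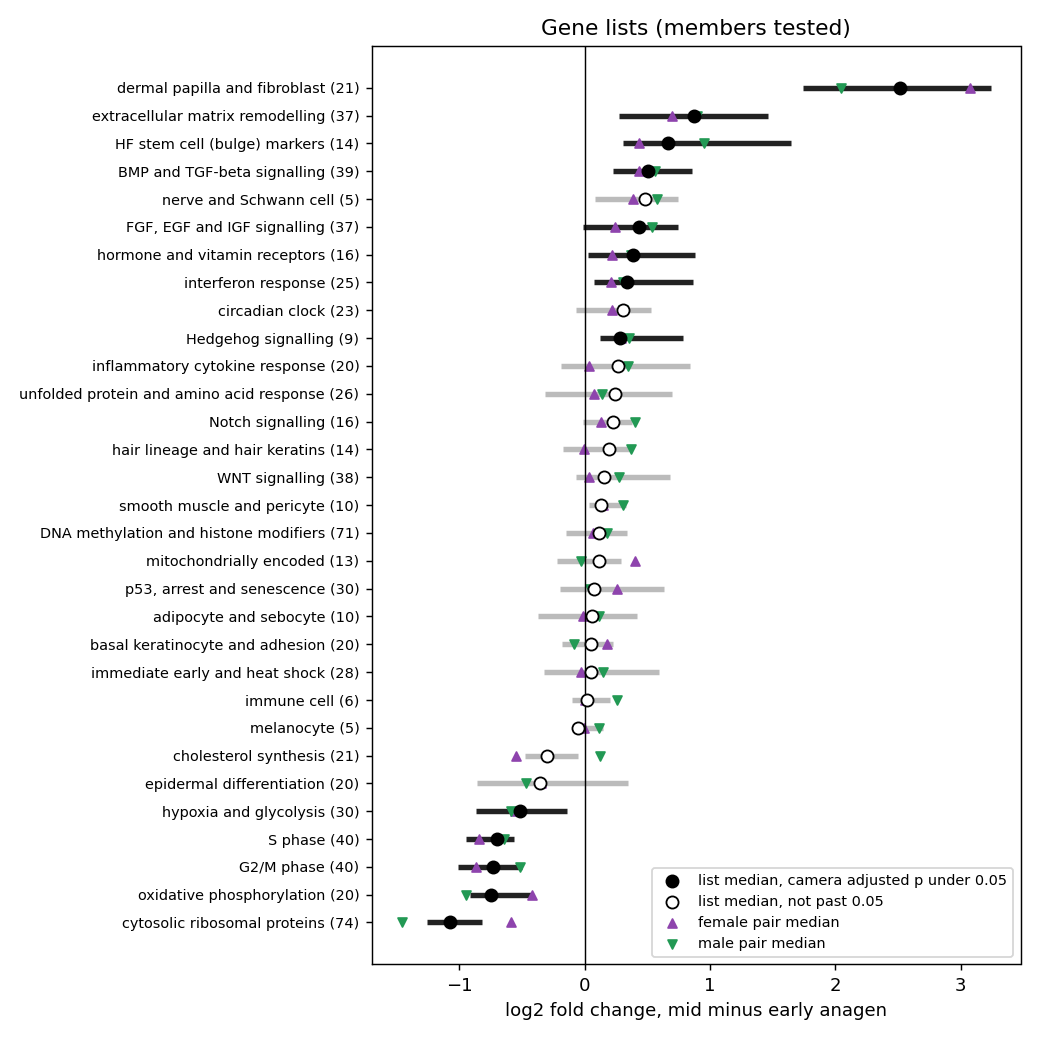
Circles are the median log2 fold change of mid against early anagen for each list, with the number of tested members beside its name, and bars span the quartiles of the members. Filled circles are the 13 lists past a camera adjusted p of 0.05, triangles pointing up are the female pair and triangles pointing down the male pair, and the medians run from -1.08 for ribosomal proteins to 2.52 for dermal papilla and fibroblast genes.

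With an estimated inter-gene correlation 0 of the 31 lists passed (2 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called only matrix remodelling (adjusted p = 0.0146). The estimate was 0.886 for the ribosomal list. It lay below the preset 0.01 for matrix remodelling (-0.0263), hormone and vitamin receptors (-0.0176), Hedgehog (-0.0055) and BMP and TGF-beta signalling (0.00678). A larger correlation among members is therefore not what ended the calls of those lists. With an estimated correlation, camera also takes its degrees of freedom from the residual of the fit, here 2. The adjusted p-values of that setting, 0.459 at the lowest, therefore do not measure co-movement of members alone. Phase coincides with the month of sampling, and no culture or library batch is given by the labels, so these cannot be separated.

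Genes related to the sex chromosomes were among those that separated male from female cells. LOC108634721, described as a Y-linked-like translation initiation factor subunit, was at 0 in both female libraries and at 66.2 and 54.8 in the early and mid male libraries. LOC108634720, a zinc finger Y-chromosomal protein, was at 0.016 and 0.022 in females and at 10.6 and 11.1 in males. In all, 6 genes with no chromosome in the ARS1.2 table were at male-only levels in both phases, as was BIN2 on chromosome 5. They were picked by the labelled sexes, so their match to the labels was fixed by the choice. Of the sex-linked genes fixed beforehand only SRY was found by its symbol, at 0 in all 4 libraries. The planned check of the sex labels by symbol could therefore not be made. The descriptions of LOC108634720 and LOC108634721, which name the Y chromosome, were not part of the choice.

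Outside these, the 5 genes taken by the rule were MAP28, LCP1, EDN1, THEM5 and CXCR4. MAP28, a cathelicidin antimicrobial peptide, was at 5.91 and 24.4 in the early and mid female and at 0.580 and 5.10 in the early and mid male libraries, a male-minus-female log2 difference of -2.09 (SE 0.16, limma adjusted p = 0.0125). LCP1, an actin-bundling protein, was higher in males by 1.95 (SE 0.18, adjusted p = 0.031), and EDN1, endothelin, by 1.81 (SE 0.17, adjusted p = 0.0379). THEM5, a thioesterase, differed by -2.18 (SE 0.22) and the chemokine receptor CXCR4 by -1.71 (SE 0.18), both at an adjusted p of 0.0473. The fit called 18 genes, 12 higher in males and 6 higher in females, of which 8 have no symbol. This balance turned after rescaling to a common total, with 166 higher in males and 231 higher in females, with a filter of 5 (42 and 59) and with pseudocounts of 0.1 (19 and 27) and 5 (19 and 29). With 1 library of each sex per phase, leaving out any library left 0 to 2 calls.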

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

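Whether the change from early to mid anagen differs between the sexes was not tested, since with 1 library per phase and sex an interaction of phase and sex leaves no residual. In 7 gene lists the median log2 fold change of mid against early anagen was above 0 in the pair of one sex and below 0 in the other, and these are given as values. The basal keratinocyte list had a median of 0.18 in the female pair and -0.0834 in the male pair. The hair lineage list was at -0.00292 in the female and 0.371 in the male pair, the melanocyte list at -0.00579 and 0.112, the adipocyte and sebocyte list at -0.0127 and 0.116, and the immediate early and heat shock list at -0.0306 and 0.143. The cholesterol synthesis list had a median of -0.545 in the female and 0.122 in the male pair. The mitochondrially encoded genes had a median of 0.402 in the female and -0.0259 in the male pair.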

How the results depend on the processing

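Rescaling to a common total, removing the span and intensity trend, and limma without an intensity trend were chosen after seeing the data. The 38 phase calls became 1782 with a replicate block, 18 with a pseudocount of 0.1, 0 of 17322 genes with no filter (3843 at an unadjusted p under 0.05), 651 after rescaling and 18 with the trend removed; leaving out a library, which takes the spread from the other phase alone, gave 0 to 733. They stayed within 1.5 times at 43 with a pseudocount of 5, 57 with a filter of 5, 30 without the intensity trend and 38 with a fold-change minimum. The 18 sex calls became 46 and 48 with pseudocounts of 0.1 and 5, 0 with no filter (1504 at an unadjusted p under 0.05), 101 with a filter of 5, 1 without phase in the fit, 397 after rescaling, 9 without the intensity trend and 10 with the span trend removed; leaving out a library gave 0 to 2, the 0 without the early female (251 at an unadjusted p under 0.05) or the mid female (108). The 13 lists became 0 with an estimated correlation and 1 with fry, and numbered 12 to 17 otherwise, not always the same lists. Rescaling kept 11 and gained epidermal differentiation (camera adjusted p = 0.0427), and the span trend removal kept 11 and gained 4. Leaving out a library also changed which lists passed, with cholesterol synthesis gained without the mid male library. As deposited, the camera adjusted p with an estimated correlation was 0.801 for epidermal differentiation and 0.811 for cholesterol synthesis. The gap between correlations within and between phases was 0.025 for all tested genes and 0.0592 for the 1000 most variable, where the mid libraries (0.9009) were less alike than the early and mid female libraries (0.9079). The cause of these changes was not tested, except that the settings leaving out a library or the filter change the libraries or genes used. The estimated correlation also changes the degrees of freedom of camera.

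No direction reversed for the named genes in any setting. The log2 fold changes of the 18 rule genes lay between 0.522 and 1.37 times the reported ones; 18 kept their call with the replicate block, 8 with a pseudocount of 0.1, 14 without the intensity trend and 9 with the span trend removed, and 0 with no filter or without either early library. In the block, same-numbered libraries deviated together with a correlation of 0.292 across genes, but with 2 pairs and no shared animal, litter or day in the labels the numbers are not shown to pair the samples; the block also gave 14 lists. The planned count-based normalisation and tests, and the transcript level, were not run, because the values are neither counts nor per transcript. The unknown depth means that a value of 0 sets no upper limit.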

Other observations

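The tests below were chosen or written after the results they bear on were seen, except the check on 29 further fibroblast genes, which was fixed before its values were seen, once a test on the 8 genes that showed the pattern had been set aside as circular. The 95% intervals are over genes, which move together within a library, so they cover the choice of genes and not the spread between libraries. Some genes outside the rule, picked here after their values were seen and not tested, had changes between the phases that lay far apart in the 2 sexes. FCGBP, a mucin-like secreted protein, was at 31.0 and 24.6 in the early and mid female and at 5.72 and 268 in the early and mid male libraries. SPP1, osteopontin, was at 6195 and 6178 in the early and mid female and at 1287 and 15389 in the early and mid male. ICAM1 was at 6.83 and 3.23 in females and 5.50 and 36.5 in males. CRCT1 went the other way, at 62.5 and 84.1 in females and 55.4 and 2.48 in males. Apart from these, LOC102186409 was called for sex in both phases together, differing by -4.72 on the log2 scale (limma adjusted p = 0.000261), with values of 228 and 133 in females and 7.21 and 4.40 in males.

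The rise of matrix genes at mid anagen may be partly a small share of fibroblasts in the cultures. For COL1A1, COL1A2, COL3A1, COL6A1, COL6A2, COL6A3, DCN and LUM, picked because of their pattern, the rise was 3.11 to 6.36 times larger in the female than in the male pair. Of the 29 further fibroblast genes, 17 reached 1 in a mid library and 15 of these were higher in both pairs (88.2%). Choosing them by their mid values favours a rise, and no share of all genes under the same choice is given for comparison. Their median ratio of 1.45 (0.952 to 2.59) did not reach 2 and its interval holds 2. For the collagen genes a phase difference and admixture therefore cannot be told apart. For 273 other genes at least 2-fold higher in both pairs the median ratio was 1.09 (95% interval 1.04 to 1.16), which lies within the interval of the 29-gene check, so the ratio cannot exclude admixture for them either, although 263 of them lay below the lowest ratio of the 8 picked genes. The 12 bulge markers higher in both pairs had a median ratio of 0.636 (0.437 to 1.1), an interval that overlaps that of the 29-gene check, so they too leave admixture open.

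For the lower ribosomal protein values, the camera adjusted p as deposited was 0.508 with an estimated correlation of 0.886. With the span trend removed the median was -0.547 (-0.631 to -0.418, camera adjusted p = 1.71e-10 at the preset correlation of 0.01). This median argues against the trend as the whole cause, although genomic span is an imperfect stand-in for transcript length and may correct too little. Against 79 other abundant genes spanning up to 1500 bp, a comparison added once that value was known, the list differed by a median of -0.338 (-0.69 to -0.128) in the male pair and -0.0829 (-0.294 to 0.078) in the female pair, where removing the trend left -0.233 (-0.339 to -0.138). Each pair is 1 library against 1 and the pairs differ, so a loss of short transcripts cannot be told apart from a change in these genes. Equal library totals left the list at -0.736 (-0.83 to -0.639), and moved the median of all tested genes from 0.01 to 0.32. The size of that shift is set by the totals, so it shows only that they are too close to account for the whole fall. The phase difference stays open and untested.

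The lower S and G2/M values were not removed with the span trend, after which the S phase median was -0.705 (-0.772 to -0.612). Fewer keratinocytes as the whole cause would lower the basal keratinocyte genes as much, and their median was 0.0519 (-0.111 to 0.21) against -0.699 (-0.832 to -0.645) for S phase, although the abundant KRT14 and KRT5 were themselves lower by -1.25 and -1.05 without passing the test. After rescaling to a common total the medians were -0.38 for S phase and -0.40 for G2/M, against 0.32 for all tested genes. The phase difference stays open and untested. For the 38 phase calls, the 4 libraries allow 3 splits into groups of 2, too few for a share under 0.05; the real split gave 38 calls and the highest other 1.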
